A study of Eutrema salsugineum and Arabidopsis thaliana with 15 samples.

How the data were processed

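Messenger RNA of rosette leaves was measured on 15 one-colour Agilent arrays. Of these, 6 came from Arabidopsis thaliana accession Col-0, a salt-sensitive laboratory plant, and 9 from Eutrema salsugineum accession Yukon, a salt-tolerant relative. Each of the 5 groups held 3 arrays, and the series text describes the replicate numbers as separate experiments, so the replicates were treated as biological. The groups and replicate numbers were taken from the sample titles. Both platforms were scanned and quantified with Agilent Feature Extraction 10.5.1.1, per the file headers. The spot values are intensities on a linear scale, per the file headers: the processed signal is a Cy3 brightness from which the software had subtracted background. The labels' protocols describe column-purified total RNA, low-input amplification and Cy3 labelling. Any further step between scan and deposit is not given in the sources used here. The series value tables held the same processed signals at 45220 of 45220 spots on each Arabidopsis array and 45217 of 45217 on each Eutrema array, with no further scaling or centring, and no sample column was left unused.

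The comparisons, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The signal of each array was taken as log2 of the processed signal minus the array's 75th percentile over non-control spots. Control spots were left out and outlier-marked spots were set to missing. Spots of one probe were averaged. A probe entered a test when it was well above background on all 3 arrays of at least 1 group. Of several probes of a gene the one with the highest mean signal was used. On the Arabidopsis array 5945 genes had several probes, and 24 of these genes had probes called in opposite directions. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) with Benjamini-Hochberg adjustment over 22074 Arabidopsis genes or 33766 Eutrema contigs, and a gene was called at an adjusted p under 0.05. The Eutrema contrasts came from one fit over all 9 arrays, so that the 3 groups shared an estimate of spread, with 6 residual and 2.81 prior degrees of freedom. The Arabidopsis fit had 4 and 3.22. Python 3.11.15 with NumPy 2.4.6 and matplotlib 3.10.9 handled tables and plots. The number of arrays, 3 per group, limits the precision of each value.

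The Arabidopsis array names 33019 genes over 43603 probes and gives probe coordinates on a genome build of January 2004, per the file headers. The 43800 probes of the custom Eutrema array carry contig names only, and 0 of 41563 contig names were found in the reference table of assembly Eutsalg1_0. The planned contrast between species by annotated locus could therefore not be made. In its place, chosen after the annotation was seen to be absent, the custom probes were aligned to the Arabidopsis probes with BLAST 2.17.0 (word size 11, expected value at most 1e-04, sense strand, at least 30 aligned bases, 80 percent identity and a lead of 5 bits over the next gene). This named 4310 of 43800 custom probes after 3115 Arabidopsis genes, with a median identity of 91.2 percent over a median of 45 bases. Genes measured on both platforms numbered 2838, and every Eutrema gene name in the text rests on this match, which can join paralogs. Adjusted p-values of named Eutrema genes and lists are over these 2838 genes. At 200 mM the matched fit called 797 of them and the platform-wide fit 721 of the 2754 whose best contig represented the contig there, 719 in common.

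The lists, 31 in number with 543 loci, were written from textbook knowledge. Of the 543 loci, 543 had a probe on the Arabidopsis array and 147 a matched Eutrema probe. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists: 30 in Arabidopsis and 11 in Eutrema, where 20 lists had too few matched members. Root markers had 2 measured members on the Arabidopsis array and were not tested. Each test was repeated with an estimated correlation. No list of any contrast held its call with an estimated correlation, and that p is given beside each call of the reported setting. Counts of members are given over all genes tested and adjusted over the list alone. The lists of guard cell, vascular, floral and root markers, leaf senescence and phase change served as signs of other tissues or of age. The genes named were the 10 sentinel genes, the 5 highest and 5 lowest called genes with a symbol or description, no overlap between groups and signal well above background in the higher group, and up to 3 called members of each list past the threshold (otherwise up to 2). For the contrast between species the non-overlap was asked of each array's response and the background rule of all 4 groups. Of these, genes that lost their call under many alternatives are given with the range of their adjusted p or only counted, where ranges of Eutrema genes leave out slide as a fixed block and only the 2 groups compared. With 3 arrays against 3 in a contrast within a species, a single unaffected gene has a chance of 10% of groups that do not overlap. This share does not hold between species, where the responses of a species were taken from the same control mean and are not independent.

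Changes are log2 fold changes ± standard error of the fit. Where a gene was not well above background on any array of a group, a bound is given as "at least N-fold": the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background, on the normalized log2 scale. Such a bound holds for the reported processing only, and the alternatives gave changes smaller than the bound for the genes where this is stated. Setting such genes to their bound moved the median of no list in the contrasts within a species. This was close to certain beforehand, since 5 Arabidopsis lists held 1 such gene each and the Eutrema lists 0.

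Replicate numbers pair the samples, because the series text ties each number to one experiment. As a check, deviations from group means of same-numbered arrays correlated at 0.23, 0.02 and 0.05 between the Arabidopsis groups, at 0.05, 0.32 and -0.14 between Eutrema control and 200 mM, at 0.00, 0.16 and -0.08 between control and 500 mM, and at 0.37, 0.24 and 0.50 between 200 and 500 mM. Of these pairs, those at 0.23 and 0.05 in Arabidopsis and at 0.50 between 200 and 500 mM also shared a slide. The reported fits did not use the pairing, and the fit with the replicate number as a block was run as an alternative. Slides held several groups on the Arabidopsis array (slide 1: control 1 and salt 1 and 2, slide 2: control 2 and 3 and salt 3). On the Eutrema array no slide held both a control and a 200 mM array, slide 5 held a control and a 500 mM array, and slides 2 and 4 each held a 200 mM and a 500 mM array. Each slide was scanned as 1 set, so slide and scan cannot be told apart.

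The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, no filter on background, a filter over every array, the mean of all probes, the replicate block, slide as a random or a fixed block, leaving out each array in turn, the series value table, eBayes without trend, an absolute log2 fold change of at least 1, only the 2 groups compared, and for the species only loci with 1 probe per platform. Added after the data were seen were a stricter sequence match (at least 45 bases and 90 percent identity), lists and overlap without Yukon_200mM replicate 3, and list medians without scaling between arrays. Shared controls were addressed with 20 simulations of unchanged groups against the same controls. The steps were tested on simulated data with 200 genes changed by known amounts. With 22074 Arabidopsis genes the fit called 12%, 64% and 84% of 50 genes changed by log2 1, 2 and 4 each, and 2.44% of its calls were false. For 33766 contigs these shares were 38%, 72% and 96% in the 200 mM contrast, 28%, 64% and 94% in the 500 mM contrast and 32%, 72% and 92% between the doses, with 3.70%, 4.12% and 6.67% of calls false, and 10% for any difference among the 3 groups. For the 2838 matched genes they were 52%, 68% and 96%, with 4.42% false. With slide as a fixed block, and a slide effect added to the simulated values, the 500 mM fit of 33766 contigs called 0% of the genes changed by log2 4. On the real arrays the same model called 4758 contigs, so this 0% is not its power there. Each simulation changed 200 genes, fewer than any real comparison called. Its adjustment was therefore stricter, and the shares above are not the power on the real arrays. Camera, run on 22074 genes, called 10 of 10 shifted lists and 0 of 20 unshifted lists. These lists were random and their simulated genes independent, so this does not show how camera treats lists whose members move together.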

Results

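The data describe rosette leaves of a salt-sensitive and a salt-tolerant plant of the same family after 1 week of sodium chloride in hydroponic culture. Arabidopsis thaliana Col-0 was sampled under control conditions (25 mM NaCl, 3 arrays) and at 200 mM (3 arrays). Eutrema salsugineum Yukon was sampled under control conditions (25 mM), at 200 mM and at 500 mM (3 arrays each). By the labels the Arabidopsis controls were 4 weeks old and the salted plants entered treatment at 24 days. For Eutrema the labels give 33 days for the controls when sampled, 29 days before 1 week at 200 mM and 35 days before 1 week at 500 mM, so dose and age moved together. On the Arabidopsis arrays 64.8% to 67.6% of spots were well above background in controls and 69.8% to 71.3% at 200 mM. The 75th percentile of the signal was 1525 to 2138 intensity units in the Arabidopsis controls and 2766 to 3781 at 200 mM, while the 100 brightest spots held 17.2% to 20.1% and 11.8% to 12.6% of the signal. On the Eutrema arrays 77.3% to 81.7% of spots were well above background in controls, 81.3% to 83.7% at 200 mM and 77.6% to 82.7% at 500 mM. Their 75th percentiles were 6324 to 8317, 8827 to 9821 and 8115 to 10831, with 6.0% to 7.0% of signal in the 100 brightest spots. Changes below are log2 fold changes of salt over control ± SE with 3 arrays per group.

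The first comparison asked how Arabidopsis leaves responded to 200 mM NaCl. The largest estimated increases were in AT5G55150, an F-box protein gene (11.64 ± 0.85, adjusted p = 4.6e-04, at least 826-fold higher), and EM1, a late-embryogenesis abundant protein of seeds (9.03 ± 0.75, at least 309-fold higher). IDL1, a gene for an abscission-type signal peptide (8.63 ± 0.79, at least 112-fold higher), and AT2G47520, an AP2-domain transcription factor (8.38 ± 0.86, at least 72.2-fold higher), were also not well above background on any control array. Their estimates and those of AT5G55150 and EM1 rest on control signals not well above background, so their rank is uncertain. Over the alternatives the estimates fell to 7.46 for AT5G55150, 5.78 for EM1, 4.65 for IDL1 and 4.21 for AT2G47520, below these bounds. ATHVA22B, of an abscisic acid-induced family, rose by 8.51 ± 0.68 and was well above background on 1 of 3 control arrays. The largest decreases were in the oxidoreductase gene AT3G46490 (-6.62 ± 0.77, well above background on 1 of 3 salted arrays), the thionin gene THI2.2 (-6.49 ± 0.49, on 2 of 3), the wall-loosening expansin ATEXPA8 (-5.80 ± 0.21), the growth-promoting regulator PRE1 (-5.66 ± 0.45) and the fatty acid desaturase ADS1 (-5.49 ± 0.93). On the January 2004 build named in the array headers, the probe of AT5G55150 lies on chromosome 5 at 22382288 to 22382347 and that of EM1 on chromosome 3 at 19215397 to 19215456. The probes of THI2.2 and ATEXPA8 lie on chromosome 5 at 14562117 to 14562290 and on chromosome 2 at 16949090 to 16949149. In total 8768 of 22074 genes were called, 4266 higher and 4502 lower, against 3445 and 5237 with scaling to the median and 3246 and 5107 with normexp background correction.

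**Figure D1:**
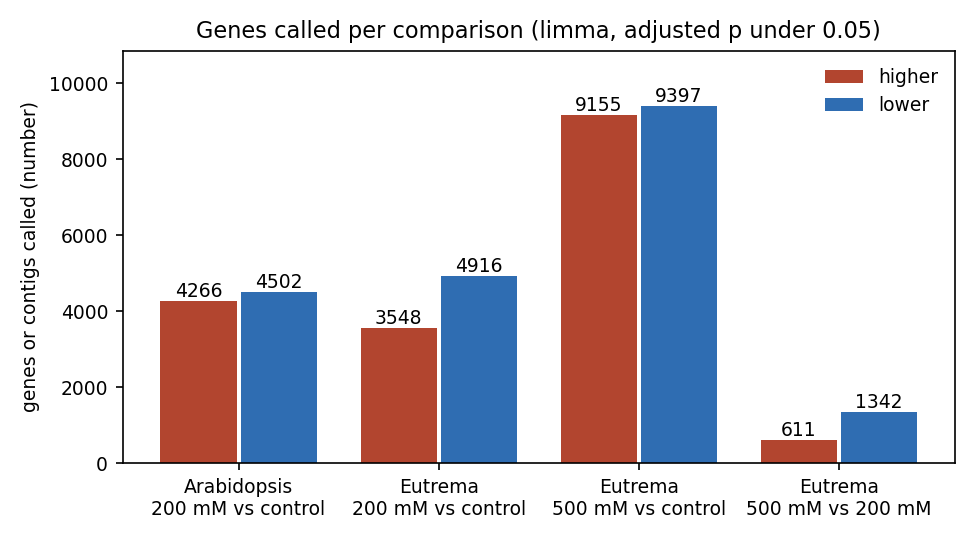
Number of genes (Arabidopsis) or contigs (Eutrema) called higher (red) or lower (blue) in each comparison by limma at an adjusted p under 0.05, 3 arrays per group. The 500 mM comparison called 9155 contigs higher and 9397 lower, against 611 and 1342 between the doses.

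Genes of the abscisic acid pathway, the hormone of water deficit, rose in Arabidopsis: 14 of 19 measured members were called higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 2.34. Camera gave an adjusted p = 8.84e-06 for this list, and an adjusted p = 0.382 with an estimated correlation. Among its members the protein phosphatase gene HAI3 (AT2G29380, well above background on 1 of 3 control arrays) rose by 6.13 ± 0.44, the hormone-degrading CYP707A1 by 4.56 ± 0.65 and the marker RD29B (LTI65) by 5.75 ± 0.56. The sentinels RD29A (LTI78, 2.52 ± 0.29), NCED3, which makes the hormone's precursor (2.72 ± 0.58), and COR15A, a chloroplast protectant (1.05 ± 0.21), were higher too. Of the 10 sentinels 7 were called higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0173, and p = 0.382 with an estimated correlation). Late-embryogenesis abundant and cold-regulated proteins were called higher for 11 of 21 and lower for 1 (13 and 1 adjusted over the list alone), led by EM6 (GEA6, 7.75 ± 0.88) and LEA7 (AT1G52690, 7.09, adjusted p = 0.00765). For that list the median was 1.05 (1.84 within slide 1 and 1.68 with quantile normalization), with a camera adjusted p = 1.32e-04 and an adjusted p = 0.449 with an estimated correlation. Proline metabolism, which handles a compatible solute, had 7 of 10 members higher and 0 lower (7 adjusted over the list alone, median 0.97, camera adjusted p = 0.0251, and p = 0.382 with an estimated correlation). Both the synthetic P5CS2 (1.51 ± 0.25) and the degrading PRODH1 (ERD5, 2.04 ± 0.41) rose. P5CS1, the rate-limiting synthetic enzyme, rose by 0.74 ± 0.20, with an adjusted p = 0.0242 that ran from 0.0152 to 0.0766 over the alternatives. The arrays of these groups also differed in signal, with 17.2% to 20.1% of it in the 100 brightest spots of controls and 11.8% to 12.6% at 200 mM, and this holds beside every Arabidopsis gene group described here.

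Stress transcription factors were higher for 15 of 21 members and lower for 0 (16 adjusted over the list alone, median 2.37, camera adjusted p = 2.9e-05, and p = 0.449 with an estimated correlation). RAP2.6 (5.90 ± 1.16) and ANAC055 (5.20 ± 0.77) led them, and MYB41 (AtMYB41), a regulator of cuticle genes, was at least 7.34-fold higher. The log2 estimate for MYB41 was 5.13 and fell to 1.26 over the alternatives, below that bound. Flavonoid and anthocyanin synthesis, the route to red pigments, was higher for 16 of 21 and lower for 0 (16 adjusted over the list alone, median 2.91, camera adjusted p = 2.13e-06, and p = 0.449 with an estimated correlation). Its regulators MYB90 (6.58 ± 0.35) and TT8 (4.97 ± 0.79) and the enzyme DFR (5.38 ± 1.00) rose, the regulators from controls well above background on 2 of 3 arrays. Heat shock and chaperone genes were higher for 7 of 13 and lower for 0 (7 adjusted over the list alone, median 1.87, and 0.97 with normexp background correction, camera adjusted p = 0.00316, and p = 0.382 with an estimated correlation). The chloroplast chaperone HSP21 rose by 6.98 ± 0.98, with 1 of 3 control arrays well above background. Leaf senescence genes were higher for 10 of 20 and lower for 0 (12 adjusted over the list alone, median 1.09, camera adjusted p = 0.00136, and p = 0.449 with an estimated correlation), with DIN2 at 5.38 ± 0.81 and the sugar exporter SAG29 at 4.72 ± 0.38.

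Photosynthesis genes fell together in salted Arabidopsis. Of 49 measured light-reaction genes, which encode antenna and photosystem proteins, 49 were called lower (49 adjusted over the list alone), with a median of -1.74. Camera gave an adjusted p = 1.98e-21 for this list, and an adjusted p = 0.382 with an estimated correlation. The antenna genes LHCB2.3 (-3.83 ± 0.34), LHB1B1 (-2.99 ± 0.35) and LHCA6 (-2.71 ± 0.22) fell most. Calvin cycle genes, which fix carbon, were lower for 20 of 23 and higher for 2 (20 and 2 adjusted over the list alone, median -1.37, camera adjusted p = 1.09e-07, and p = 0.382 with an estimated correlation). Among them GAPA-2 (-2.35 ± 0.27) and CP12-2 (-2.23 ± 0.18), a regulator of the cycle, fell most. These are bright genes, and the salted arrays had brighter 75th percentiles and less of their signal in the brightest spots, and with scaling to the median the median of all genes was -0.13. The light-reaction median was -0.85 and the Calvin cycle median -0.53 with quantile normalization, and -0.89 and -0.51 without scaling between arrays. Within slides 1 and 2 the light-reaction median was -1.85 and -1.79, and -1.82 with slide as a block.

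**Figure D2:**
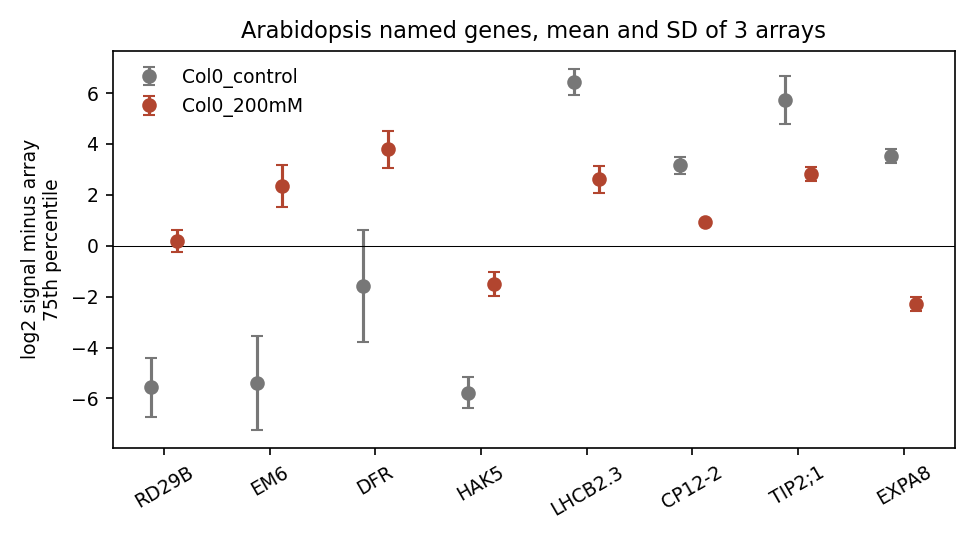
Mean and SD over 3 arrays of the log2 signal, minus each array's 75th percentile, of 8 Arabidopsis genes in control (grey) and 200 mM NaCl (red). RD29B, EM6, DFR and HAK5 were higher with salt, and LHCB2.3, CP12-2, TIP2;1 and EXPA8 lower.

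Aliphatic glucosinolate synthesis, which makes defence compounds from methionine, fell for 18 of 19 members and rose for 0 (19 adjusted over the list alone, median -1.52, camera adjusted p = 8.07e-09, and p = 0.382 with an estimated correlation), with CYP79F1 at -2.05 ± 0.21 and the transporter BAT5 (AT4G12030) at -1.93 ± 0.21. Aquaporins, the water channels of membranes, were lower for 12 of 19 and higher for 1 (13 and 3 adjusted over the list alone, median -1.27, and -0.74 with quantile normalization, camera adjusted p = 5.45e-04, and p = 0.382 with an estimated correlation). The vacuolar DELTA-TIP (-2.90 ± 0.44) and the plasma membrane PIP1;5 (-1.88 ± 0.15) were among them. Cell wall expansion genes were lower for 11 of 19 and higher for 2 (11 and 2 adjusted over the list alone, median -1.34, and -0.71 within slide 2, camera adjusted p = 0.00457, and p = 0.458 with an estimated correlation). XTH6 (AT5G65730), which remodels xyloglucan, changed by -3.84 ± 0.22, whereas the expansin ATEXPA10 rose by 2.91 ± 0.45. Markers of 2 other leaf tissues fell: vascular genes for 6 of 10 members (7 adjusted over the list alone, median -1.05, camera adjusted p = 0.0208, and p = 0.382 with an estimated correlation) and guard cell genes for 4 of 10, with 1 higher (4 and 1 adjusted over the list alone, median -0.75, and -1.64 within slide 1, camera adjusted p = 0.0438, and p = 0.449 with an estimated correlation). XCP1, a protease of maturing vessels (-2.81 ± 0.44), and the guard cell potassium channel KAT1 (-1.92 ± 0.22) were lower. Without scaling between arrays the medians of the aquaporin, wall, glucosinolate and vascular lists were -0.41, -0.49, -0.67 and -0.20, and that of the guard cell list turned to 0.11, while those of the late-embryogenesis, proline, senescence and sentinel lists were 1.91, 1.82, 1.94 and 1.78.

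Ion transport genes moved both ways in Arabidopsis, with 9 of 28 higher and 5 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.32, median 0.20). The high-affinity potassium transporter HAK5 rose by 4.27 ± 0.39 and the vacuolar sodium antiporter NHX1 by 0.80 ± 0.16. HKT1, which retrieves sodium from the xylem, was at least 7.64-fold lower and not well above background on any salted array (adjusted p = 5.1e-04). Its log2 estimate of -4.29 shrank to -1.86 over the alternatives, short of that bound. The plasma membrane antiporter SOS1 (0.07 ± 0.18, adjusted p = 0.779) and the galactinol synthase AtGolS2 (0.39 ± 0.48, adjusted p = 0.558) did not pass the test. Sugar and raffinose metabolism had 10 of 33 members higher and 5 lower (10 and 6 adjusted over the list alone, camera adjusted p = 0.45), with AtGolS4 at 5.17 ± 0.27 and the sucrose synthase SUS3 at 4.41 ± 0.31, and a list median of -0.01, against a mean of 0.38, that changed sign with the scaling. Limma called 5798 genes without Col0_200mM replicate 3, which was the only left-out array to move the count of 8768 by over 1.5 times.

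The second comparison asked how Eutrema responded to the same 200 mM. The lipid transfer protein gene LTP3 (6.07 ± 0.63, adjusted p = 0.00113) and its relative AT5G59330 (6.04 ± 0.59) rose most among matched genes. They were followed by AT2G47770, a benzodiazepine receptor-related membrane protein (5.76 ± 0.83), the acyltransferase GPAT2 (5.56 ± 0.36) and the signal peptide gene CLE14 (5.24 ± 0.63). On the control arrays GPAT2 and ABI5 were well above background on 1 of 3 and CLE14 and RD29A (LTI78) on 2 of 3, which holds for both doses. The largest decreases were in SP1L4, of a microtubule-associated family (-2.94 ± 0.57), the pectinesterase AT2G45220 (-2.65 ± 0.69, adjusted p = 0.0235, 0.0136 to 0.065 over the alternatives), the germin GER3 (-2.36 ± 0.50), AT1G04530 (-2.30 ± 0.27) and the myrosinase-associated AT1G54010 (-2.27 ± 0.41). Of 33766 contigs 8464 were called, 3548 higher and 4916 lower, against 2655 higher and 6082 lower with scaling to the median. Limma called 4105 contigs without Yukon_control replicate 2, 5124 without Yukon_control replicate 3 and 5480 without Yukon_200mM replicate 1.

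In Eutrema at 200 mM, 38 of 38 matched light-reaction genes were lower (38 adjusted over the list alone, median -0.94, camera adjusted p = 1.7e-15, and p = 0.301 with an estimated correlation). LHCA6 (-1.71 ± 0.27) and LHCB2.3 (-1.58 ± 0.33) were among them, and the list median was -0.39 with quantile normalization and -0.60 without scaling between arrays, on arrays whose 75th percentile (8827 to 9821) lay above that of every control (6324 to 8317). Calvin cycle genes were lower for 8 of 11 and higher for 0 (10 adjusted over the list alone, camera adjusted p = 1.64e-04, and p = 0.301 with an estimated correlation), with SBPASE at -1.31 ± 0.18 and PGK1 at -1.08 ± 0.17, but the list median of -0.45 was -0.11 without scaling and turned to 0.03 under quantile normalization. Abscisic acid genes were higher for 4 of 5 and lower for 0 (4 adjusted over the list alone, median 2.102, camera adjusted p = 0.0026, and p = 0.319 with an estimated correlation). The transcription factor ABI5 rose by 3.58 ± 0.47 and the phosphatase ABI1 by 2.28 ± 0.51. Flavonoid genes were higher for 4 of 7 and lower for 0 (4 adjusted over the list alone, median 2.35, and 1.21 with normexp background correction, camera adjusted p = 0.00666, and p = 0.319 with an estimated correlation), among them UGT78D2 (4.01 ± 0.65) and DFR (3.84 ± 0.58). Aquaporins were lower for 4 of 9 and higher for 0 (7 adjusted over the list alone, median -0.98, and -0.64 without scaling, camera adjusted p = 0.00312, and p = 0.301 with an estimated correlation), with DELTA-TIP at -2.12 ± 0.37, and under quantile normalization camera gave an adjusted p = 0.0553. The sentinels RD29A (LTI78, 2.26 ± 0.84, adjusted p = 0.0736) and PRODH1 (ERD5, 0.21 ± 0.45, adjusted p = 0.757) did not pass the test. Yukon_200mM replicate 3 lay apart from its group: it correlated at 0.974 to 0.975 with the 500 mM arrays and at 0.941 to 0.951 with replicates 1 and 2 of its own group. Without it limma called 6689 contigs, and with slide as a fixed block 0, where 5438 had an unadjusted p under 0.05.

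The third comparison set Eutrema at 500 mM, a dose near that of seawater, against the same controls. AT2G47770 rose by 8.39 ± 0.83 (adjusted p = 1.25e-04), LTP3 by 7.66 ± 0.63, AT5G59330 by 7.57 ± 0.59, GPAT2 by 7.28 ± 0.36 and the alcohol dehydrogenase ADH1, well above background on 2 of 3 controls, by 6.27 ± 0.83. GER1, a germin-like protein gene (-6.98 ± 1.28, well above background on 2 of 3 salted arrays), the pectinesterase AT2G45220 (-5.79 ± 0.69) and the xyloglucan enzyme XTH9 (-5.61 ± 0.48) fell. The transcription factor ATRL6 was at least 39.1-fold lower and the auxin-responsive AT5G18050 at least 34.8-fold lower. Over the alternatives their log2 estimates shrank to -4.77 and -4.64, short of these bounds. RD29A (LTI78, 4.51 ± 0.84) and PRODH1 (ERD5, 1.61 ± 0.45) both rose at this dose. Of 33766 contigs 18552 were called, 9155 higher and 9397 lower.

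At 500 mM, 38 of 38 light-reaction genes were lower (38 adjusted over the list alone, median -1.94, camera adjusted p = 6.07e-15, and p = 0.417 with an estimated correlation), led by PSBQA (-3.49 ± 0.38), a subunit of the oxygen-evolving complex. The median was -1.29 with quantile normalization and -1.85 within slide 5, the only slide with a control and a 500 mM array. Abscisic acid genes were higher for 5 of 5 (5 adjusted over the list alone, median 3.62, camera adjusted p = 0.00345, and p = 0.417 with an estimated correlation), with ABI5 at 5.34 ± 0.47. Flavonoid genes were higher for 5 of 7 and lower for 1 (5 and 1 adjusted over the list alone, median 3.52, camera adjusted p = 0.0454, and p = 0.444 with an estimated correlation). The flavonoid call was lost with the replicate block (adjusted p = 0.0617), with quantile normalization (0.0811) and without Yukon_200mM replicate 3 (0.0565). Calvin cycle genes were lower for 9 of 11 and higher for 0 (9 adjusted over the list alone, camera adjusted p = 0.00345, and p = 0.417 with an estimated correlation), with GAPA at -2.46 ± 0.38, but their median of -0.55 was -0.22 without scaling and turned to 0.02 under quantile normalization. Aquaporins were lower for 6 of 9 and higher for 0 (6 adjusted over the list alone, median -0.99, camera adjusted p = 0.0285, and p = 0.417 with an estimated correlation), with DELTA-TIP at -3.45 ± 0.37 and TIP2, another vacuolar channel, at -3.15 ± 0.42, and under quantile normalization camera gave an adjusted p = 0.181. The transcription factor ATHB-7 (5.12 ± 0.65) and the dehydrin ERD10 (4.88 ± 0.75) rose, whereas XTH8 (AT1G11545, -4.06 ± 0.52) fell. With slide as a fixed block 4758 contigs were called.

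**Figure D3:**
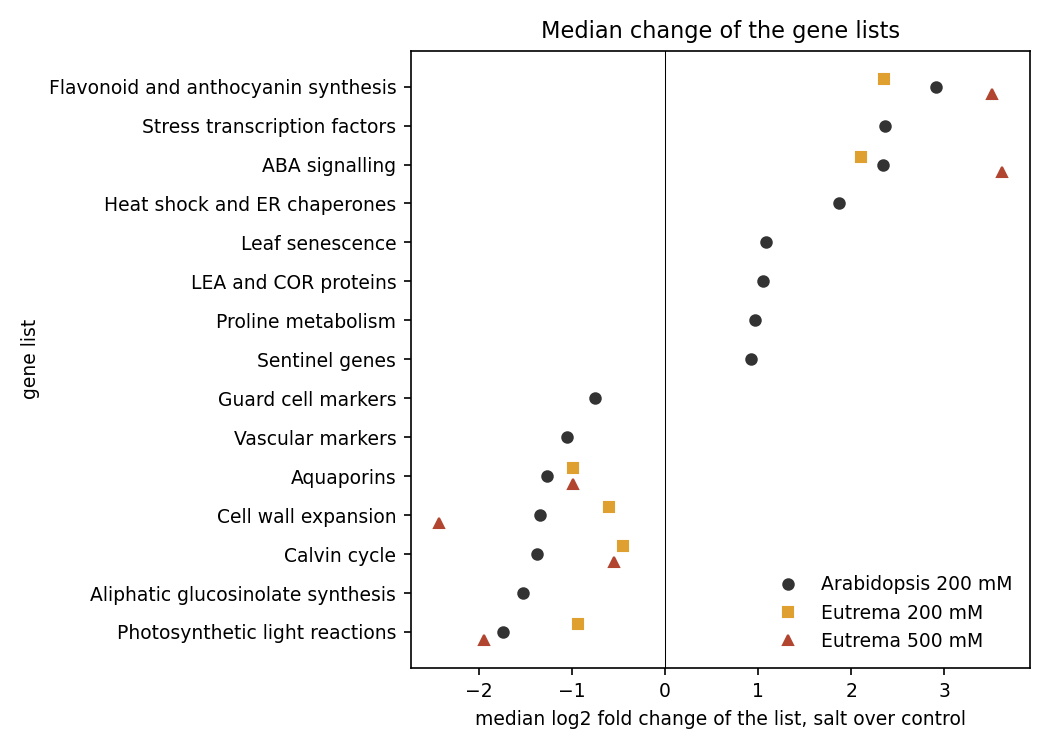
Median log2 fold change of salt over control for the 15 lists past the threshold in Arabidopsis at 200 mM (circles), and for those of them tested in Eutrema at 200 mM (squares) and 500 mM (triangles). Light-reaction medians were -1.74, -0.94 and -1.94, and the Calvin cycle medians of Eutrema turned slightly positive under quantile normalization.

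The fourth comparison set the doses against each other in Eutrema. The proteinase inhibitor ATTI1 (1.78 ± 0.43, adjusted p = 0.0424), GPAT2 (1.73 ± 0.36), the carotene hydroxylase BETA-OHASE_1 (1.71 ± 0.31) and the iron store ATFER2 (1.64 ± 0.38) were higher at 500 mM than at 200 mM. Over the alternatives other than slide as a fixed block and only the 2 groups compared, the adjusted p of ATTI1 ran from 0.0246 to 0.141, of GPAT2 from 0.00179 to 0.125, of BETA-OHASE_1 from 0.00357 to 0.116 and of ATFER2 from 0.0101 to 0.122. The xyloglucan enzymes XTH33 (-3.71 ± 0.85) and XTH9 (-3.51 ± 0.48), the pectinesterase AT2G45220 (-3.14 ± 0.69) and AT2G45180, of a lipid transfer protein family (-2.44 ± 0.34), were lower, and their adjusted p ran up to 0.137, 0.0862, 0.13 and 0.0862. Light-reaction genes were lower for 22 of 38 and higher for 0 (33 adjusted over the list alone, median -0.90, camera adjusted p = 1.17e-15, and p = 0.756 with an estimated correlation), with PSBQA at -1.84 ± 0.38 (adjusted p = 0.0348, 0.00286 to 0.122 over the alternatives), and their median was -0.64 and -0.82 within slides 2 and 4. Abscisic acid genes were higher for 1 of 5 and lower for 0 (4 adjusted over the list alone, median 1.46, camera adjusted p = 0.00574, and p = 0.756 with an estimated correlation), and their median was 1.68 within slide 2 and 0.24 within slide 4, where 1 of 5 was lower. The called member was the phosphatase HAB1 (1.46 ± 0.37, adjusted p = 0.0489, 0.00333 to 0.167 over the alternatives). In all 1953 of 33766 contigs were called, 611 higher and 1342 lower, 3490 with the replicate block, and 0 with slide as a fixed block or with only the 2 groups compared. In these last fits 0 of the 17 genes named for this contrast kept their call, at an adjusted p of 0.105 to 0.279 and 0.0787 to 0.112, and 17 kept their direction. The number of calls varied with the arrays used: limma called 9318 contigs without Yukon_200mM replicate 3, 441 without Yukon_control replicate 1 and 0 without any 1 of the other 7 arrays, where 5887 to 9525 contigs had an unadjusted p under 0.05. Named genes kept their direction over the alternatives, with XTH9 at -4.11 to -3.17 and GPAT2 at 1.47 to 2.15.

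**Figure D4:**
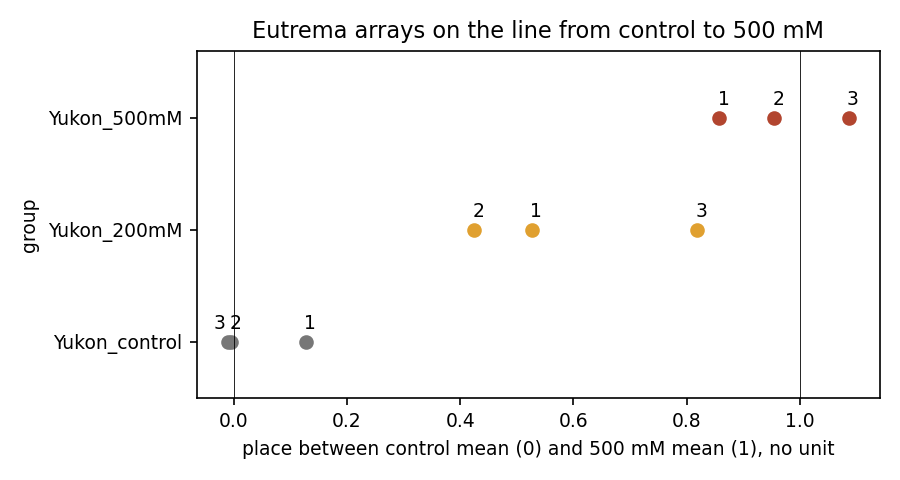
Place of each of the 9 Eutrema arrays, numbered by replicate, on the line from the control mean (0) to the 500 mM mean (1) over 33701 contigs, each array placed without itself. Yukon_200mM replicate 3 lay at 0.818, above replicates 1 (0.527) and 2 (0.424).

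Across the 3 Eutrema groups the moderated F test of limma called 15761 of 33766 contigs, and 3780 with slide as a fixed block. The doses moved largely the same contigs: 3380 were higher and 4810 lower at both, against 962 and 1368 for independent lists, and 1 contig was called in opposite directions. The changes correlated across contigs at 0.919 with a covariance of 1.38. Unchanged groups simulated against the same controls gave a correlation of 0.501 and a covariance of 0.0631. Without Yukon_200mM replicate 3, 2569 were higher and 3632 lower at both, 34 were opposite, and the correlation and covariance were 0.785 and 1.11. The 3 controls could not be split, so part of the excess may come from the shared controls.

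The fifth comparison asked whether the species differed in their response to 200 mM, over 2838 sequence-matched genes. The changes correlated at 0.637 (Spearman 0.609) across genes, which are not independent replicates, with a slope of 0.474 of Eutrema on Arabidopsis. Of 543 genes called in both, 516 (95%) changed in the same direction, 173 higher and 343 lower, against 54.1 and 124 for independent lists. At 500 mM the correlation was 0.597 (Spearman 0.578) and the slope 0.700, and 771 of 844 genes called in both (91.4%) shared a direction. Scatter across genes lowers such slopes, so by themselves they do not show a weaker response in Eutrema. A limma contrast of the responses called 409 genes, 292 with a more positive and 117 with a more negative response in Eutrema. It came from a fit over all 15 arrays, in which both platforms shared the estimate of spread of each gene. Whether the spread is equal on the platforms was not tested, and the SE and adjusted p of each difference rest on it. By the sign of the estimates, 127 of these had negative changes in both species, larger in Arabidopsis, and 42 positive ones, larger in Arabidopsis. Another 149 had a positive change in Eutrema and a negative one in Arabidopsis, 72 the opposite, and 16 positive and 3 negative changes were larger in Eutrema. Light-reaction genes fell less in Eutrema for 16 of 38 members and more for 0 (27 adjusted over the list alone, median difference 0.76, camera adjusted p = 3.84e-08, and p = 0.586 with an estimated correlation), with LHCB2.3 at 2.24 ± 0.51. With quantile normalization that median was 0.29 and without scaling 0.25, while the median of all 2838 differences was 0.18 as reported and 0.08 with quantile normalization. Calvin cycle genes had a more positive response in Eutrema for 7 of 11 and a more negative one for 0 (9 adjusted over the list alone, median 0.77, camera adjusted p = 7.12e-04, and p = 0.483 with an estimated correlation), with a median of 0.22 and an adjusted p = 0.157 under quantile normalization and a median of 0.26 without scaling. The cysteine protease XCP1 of vessels differed by 3.30 ± 0.48, at -2.81 in Arabidopsis and 0.48 in Eutrema, and AT2G45220 by -5.71 ± 0.88, at 3.06 and -2.65. The count was 158 for loci with 1 probe per platform and 127 with the stricter sequence match, and both ran over fewer genes, 1215 and 933. It was 221 without Col0_200mM replicate 3, 224 without Yukon_control replicate 2 and 260 without Yukon_control replicate 3.

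**Figure D5:**
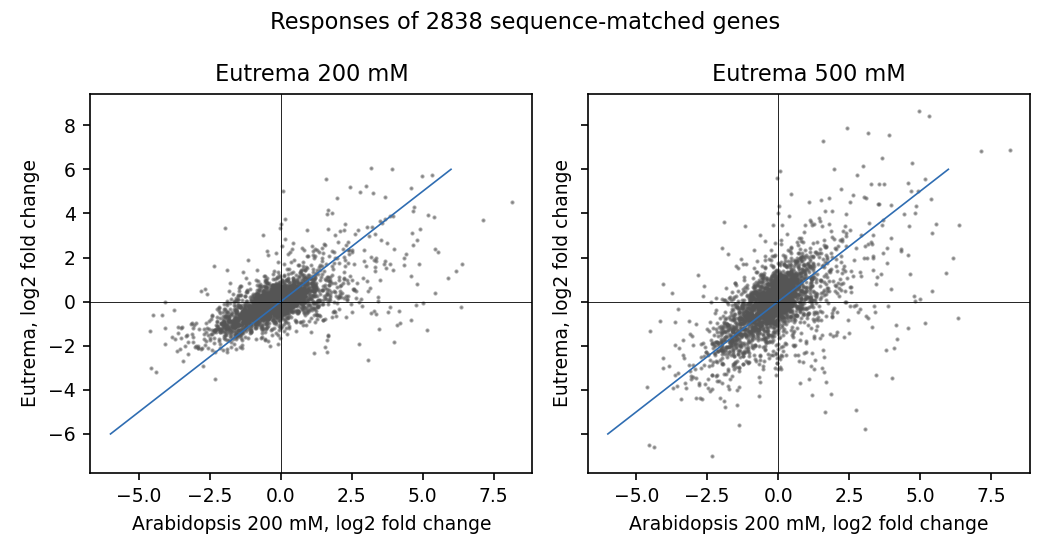
Each point is 1 of 2838 sequence-matched genes, with its log2 fold change in Arabidopsis at 200 mM (x axis) against that in Eutrema at 200 mM (left) or 500 mM (right), and the blue line marks equal change. The slopes were 0.474 and 0.700 and the correlations 0.637 and 0.597, and scatter across genes lowers such slopes.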

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

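The contrast of species was chosen after the annotation was seen to be absent, and the tests of a swap, a shared slide and a shift of the experiment with replicate number 3 after the results were seen. A limma contrast of the 200 mM responses called 409 of 2838 sequence-matched genes as different between the species. All differences here are Eutrema minus Arabidopsis on the log2 scale, and 19 of the 29 genes named held their call in the alternatives run on single genes.

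Transcripts with the most positive difference were the lipid-associated AT2G22170 (5.30, at -1.97 in Arabidopsis and 3.34 in Eutrema), the mitochondrial carrier AT5G26200 (4.06), the cysteine proteinase AT2G27420 (3.92), the auxin-responsive AT5G18030 (3.56) and TCL1, a regulator of leaf hairs (3.38). The most negative were the myrosinase PYK10 (-5.84, adjusted p = 0.0481, 0.00399 to 0.119 over the alternatives), the pectinesterase AT2G45220 (-5.71), the subtilisin-like protease NP230573 (-5.39), the transporter ABCB4 (-5.06), whose Arabidopsis probes ran from 0.03 to 5.43, and the small secreted LCR67 (-4.85). Vessel protease XCP1 differed by 3.30 and the anthocyanin transferase ATGSTF12, known as TT19, by -4.57, at 4.16 in Arabidopsis and -0.41 in Eutrema. The anthocyanin regulator PAP1 differed by -2.14, with an adjusted p of 0.0025 that ran to 0.757 over the alternatives. Lipid transfer genes went both ways, with LTP2 at -3.08 and LTP3 at 2.91 (adjusted p = 0.0266, 0.00593 to 0.0727 over the alternatives). The iron superoxide dismutase FSD1 (2.32), the thylakoid ascorbate peroxidase TAPX (1.98), the aquaporin PIP1;5 (1.83) and the calcium sensor CBL10 (1.41) had more positive responses in Eutrema. Several calls lay near the threshold: COR47 (2.49, adjusted p = 0.0493, 0.00773 to 0.211), MYB28, a regulator of aliphatic glucosinolates (1.61, 0.0374, 0.00737 to 0.0985), the nitrate transporter AT4G21680 (-4.80, 0.0412, 0.00347 to 0.104) and GDH2 (-1.77, 0.0471, 0.00273 to 0.124).

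The median difference over 38 light-reaction genes was 0.76 (camera adjusted p = 3.84e-08, and p = 0.586 with an estimated correlation), with LHCB2.3 at 2.24, LHB1B1 at 2.03 and PSAD-2 at 1.55. That over 11 Calvin cycle genes was 0.77 (camera adjusted p = 7.12e-04, and p = 0.483 with an estimated correlation), and 0.22 with an adjusted p = 0.157 under quantile normalization. Its members included the aldolases AT2G21330 (1.27, adjusted p = 0.00811, 0.00329 to 0.305 over the alternatives) and AT4G38970 (0.96, 0.00674, 0.00178 to 0.246) and PGK1 (0.94, 0.0349, 0.00845 to 0.0893). Cytosolic ribosomal proteins differed by -0.28, by -0.47 with quantile normalization and by -0.79 without scaling (camera adjusted p = 0.0499, and p = 0.717 with an estimated correlation), and lost the call without Yukon_200mM replicate 3 (0.0603).

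The light-reaction difference shrank to 0.287 with quantile normalization, so much of it depended on the scaling. There camera at its preset correlation still gave an adjusted p = 0.0181, which argues against the scaling as its whole cause only under that preset. With an estimated correlation the list had p = 0.586 in the reported scaling. Inexact probe matches are argued against, for the list genes that met the stricter match, by their median of 0.736. The stricter match can still join paralogs, and the list genes that did not meet it stay untested. Of 10000 random lists of like signal 99.97% lay below the reported difference of 0.76, but those lists had a median of 0.52 and so may hold most of the value. Their members were not chosen to move together, as light-reaction genes do, so this share cannot decide on a shift common to bright genes. Signal compression stays open: it would give larger differences for brighter Eutrema probes, and the Spearman correlation over the 38 genes was -0.260 with a permutation p = 0.114. Platform, plant age and species cannot be separated by this design, so a biological difference between the species stays untested against them.

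Over 100 splits of the arrays within species 8 gave as many genes as the contrast of species, and the highest other split gave 1414 against 409, but these splits do not show whether chance can be excluded. Those that call several times the real count point to a structure of the samples: exchanging salt and control in all Eutrema arrays adds the responses of both species and gave 1414. Of the 32 splits that part every same-numbered pair 5 called as many, the real one among them, and the other 4 kept the Arabidopsis arrays in place and exchanged 2 or 3 pairs of Eutrema.

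Yukon_200mM replicate 3 resembled the 500 mM arrays. It lay at 0.818 on the line from the control mean (0) to the 500 mM mean (1), with replicates 1 and 2 at 0.527 and 0.424 and the 500 mM arrays at 0.857, 0.954 and 1.09. A swap with a 500 mM array is argued against, since each 500 mM array correlated better with its own group than with Yukon_200mM replicates 1 and 2, by at least 0.0282. A shared slide and a shift of the experiment with replicate number 3 cannot be told apart here and stay open: its correlation with the 500 mM array of its own slide lay -0.00136 from the highest with other slides, and replicate 3 was highest in 1 of the other 2 groups, yet its deviations from the group mean correlated at 0.499 with that array, which is also replicate 3, and at -0.384 and -0.0917 with the others. Deviations within a group sum to 0, so these negative values are tied to the positive one and add no separate evidence. A single wrong label could account for it and stays open, since 0.818 lay below the lowest 500 mM array by less than their SD, as does a stronger response of those plants, which no test addressed.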

How the results depend on the processing

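The stricter sequence match and the tests without Yukon_200mM replicate 3 for gene lists and overlap were chosen after the results were seen, and the species alternatives after the annotation was seen to be absent. Within 1.5 times of the reported count stayed 12 of 12 other settings in Arabidopsis, 11 of 13 in Eutrema at 200 mM, 11 of 13 at 500 mM, 7 of 13 between the doses, 10 of 11 for any difference among the 3 groups and 11 of 13 for the contrast of species. Slide as a fixed block gave 0 contigs at 200 mM and 0 between the doses (5438 and 5986 at an unadjusted p under 0.05 by limma), 4758 at 500 mM and 3780 for any difference. No slide held both a control and a 200 mM array, but slide 5 held a control and a 500 mM array. Slides 2 and 4 each held a 200 mM and a 500 mM array, so the missing pair does not account for all these losses. An absolute log2 fold change of at least 1 left 4741, 11497 and 1136 contigs at 200 mM, at 500 mM and between the doses, since it calls a part of the same contigs. Between the doses the replicate block gave 3490, no filter on background 1275, eBayes without trend 1265 and only the 2 groups compared 0 (8008 unadjusted), and the cause was not tested. The contrast of species gave 158 genes for loci with 1 probe on each platform and 127 with the stricter match, which tested fewer genes (1215 and 933 of 2838). Leaving out 1 array at a time gave 5798 (Col0_200mM replicate 3) to 9646 genes in Arabidopsis and 4105 (Yukon_control replicate 2) to 8602 contigs in Eutrema at 200 mM, with 5124 without Yukon_control replicate 3 and 5480 without Yukon_200mM replicate 1. It gave 15041 to 20039 at 500 mM, 11156 to 18509 for any difference, and 0 to 9318 (Yukon_200mM replicate 3) between the doses, with 441 without Yukon_control replicate 1 and 0 without any other array. For the species it gave 221 (Col0_200mM replicate 3) to 464, with 224 and 260 without Yukon_control replicates 2 and 3. With an estimated correlation camera called 0 lists in all 5 contrasts, against 15 of 30 in Arabidopsis and 5, 5, 2 and 3 of 11 in the others, and with quantile normalization 2 at 500 mM. Quantile normalization gained the antioxidant (adjusted p = 0.00565), ribosomal (0.0175) and cell cycle (0.0175) lists in Arabidopsis and the wax list in Eutrema at 200 mM (0.0346). Quantile normalization reversed the Calvin cycle median in Eutrema to 0.0266 at 200 mM (adjusted p = 0.709) and 0.0244 at 500 mM (0.801), and the mean of all probes reversed RPL23AA at 500 mM to 0.15 (adjusted p = 0.494), where the cause was not tested. The replicate block changed the call of the clock and cell cycle lists in Arabidopsis (gained, adjusted p = 0.0276 and 0.0484) and of the flavonoid list at 500 mM (lost, 0.0617), and no other list call. Of the named calls, 71 of 83 in Arabidopsis, 24 of 43 in Eutrema at 200 mM, 45 of 52 at 500 mM, 0 of 17 between the doses and 19 of 29 between the species held in every alternative run on single genes that measured the gene. Some alternatives did not measure every named gene. These alternatives left out the fold threshold and, for Eutrema, slide as a fixed block (0, 30 and 0 kept at 200 mM, at 500 mM and between the doses) and only the 2 groups compared (35, 51 and 0 kept). Signal over background limits the genes given as bounds, and with 3 arrays per group the number of arrays limits every count.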

Other observations

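Single defence and nutrient genes of Arabidopsis changed at 200 mM, where 8768 of all 22074 genes were called, in lists that did not pass the threshold as reported. Camalexin synthesis, a phytoalexin route, had CYP71A13 at 4.24 ± 0.93 and PAD3 at 3.69 ± 0.73. Their list, which joins indole glucosinolate and camalexin synthesis, had 3 of 9 members higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.506). In the salicylic acid list FMO1 rose by 5.48 ± 0.80 while ACD6 changed by -2.78 ± 0.64 (6 of 16 higher and 2 lower, 8 and 3 adjusted over the list alone, camera adjusted p = 0.32). Jasmonate genes were higher for 8 of 21 and lower for 4 (9 and 4 adjusted over the list alone, camera adjusted p = 0.523), with the repressor JAZ10 at 3.08 ± 0.71. The nitrate transporter AT4G21680, known as NRT1.8, rose by 6.17 ± 1.19 in a nitrogen list with 2 of 16 higher and 5 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.386). Phosphate starvation genes included RNS1 (2.81 ± 0.53) and the galactolipid synthase MGDC (2.68 ± 0.46), with 3 of 10 higher and 3 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.936). Among 9 iron genes, 3 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.829), NAS4 changed by -2.46 ± 0.33 and the ferritin ATFER1 by 1.97 ± 0.34, with probes from -1.94 to 2.75. Antioxidant genes held the transferase ATGSTU25 (5.85 ± 0.75) and TAPX (-3.05 ± 0.22), with 7 of 26 higher and 5 lower (8 and 5 adjusted over the list alone, camera adjusted p = 0.391), and with quantile normalization the list passed (median 0.54, adjusted p = 0.00565), against p = 0.518 with an estimated correlation in the reported normalization. Wax and cutin genes held LTP4 (5.31 ± 0.46) and GPAT8 (-3.53 ± 0.48), with 4 of 21 higher and 7 lower (4 and 9 adjusted over the list alone, camera adjusted p = 0.386). Medians and means differed in sign for the nitrogen (-0.35 and 0.13), phosphate (-0.17 and 0.33) and wax (-0.46 and 0.01) lists.

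Floral organ genes were called higher for 2 of 7 and lower for 2 (2 and 2 adjusted over the list alone, camera adjusted p = 0.992), with the petal regulator PI at 3.27 ± 0.45 and a list median of -0.28, against a mean of 0.72, that changed sign with the scaling. Flowering and phase change genes were lower for 2 of 12 and higher for 0 (0 and 0 adjusted over the list alone, camera adjusted p = 0.391), with MAF5 at -0.99 ± 0.29 (adjusted p = 0.0311, 0.0169 to 0.121 over the alternatives) and SPL3 at -0.80 ± 0.20 (0.02, 0.0144 to 0.0672). Circadian clock genes were higher for 4 of 16 and lower for 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0873), with LHY at 1.12 ± 0.22, and cell cycle genes lower for 4 of 12 (4 adjusted over the list alone, camera adjusted p = 0.0541). The replicate block brought both past the threshold (adjusted p = 0.0276 and 0.0484), and quantile normalization the cell cycle list (0.0175), against p = 0.496 for the clock and p = 0.71 for the cell cycle with an estimated correlation in the reported normalization. In Eutrema the ferritin ATFER1 rose by 1.99 ± 0.35 at 200 mM and 2.82 ± 0.35 at 500 mM, and the dismutase CSD2 changed by -2.17 ± 0.42 and -2.14 ± 0.42. At 500 mM the cytokinesis gene SYP111 (-2.04 ± 0.40) and the nitrite reductase NIR1 (-1.65 ± 0.30) were lower.

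The test of dose along the Arabidopsis response was chosen after the result was seen. Across 2838 matched genes, the change of each Eutrema array had a slope on the Arabidopsis change of 0.489, 0.383 and 0.550 at 200 mM and of 0.696, 0.660 and 0.744 at 500 mM. The smallest slope at 500 mM exceeded the largest at 200 mM by 0.109, which is consistent with the hypothesis that the part of the response shared with Arabidopsis may grow with dose. Age moved with dose and the 3 controls are shared, so a growth of the response with dose stays a hypothesis.

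Other splits of the arrays called fewer genes than the real groups in these comparisons. In Arabidopsis 1 of 10 splits, the real one, called 8768, and the highest other 0. In Eutrema 1 of 10 did so at 200 mM (8464, highest other 1), at 500 mM (18552, highest other 0) and between the doses (1953, highest other 42), and 10 splits are too few for a share under 0.05. For any difference among the 3 groups 1 of 100 splits called as many as 15761, the real one, and the highest other called 10191. This argues against a random grouping of the arrays there, but the splits cannot separate dose from slide or age. Of splits that part every same-numbered pair, 1 of 4 in each of the comparisons of 2 groups (highest other 0) and 1 of 36 for any difference called as many, the real one.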
